A study of Homo sapiens with 3 samples.

How the data were processed

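RNA from SH-SY5Y cells, a human neuroblastoma line differentiated with retinoic acid, was measured on 3 one-colour Agilent arrays, 1 for each exposure time (0, 2 and 6 h) to 3 mM norephedrine. Samples were grouped by the exposure time in their labels, and the 0 h array is also called a control in the deposited files. Per the labels' protocols, total RNA was copied into Cy3-labelled cRNA from a poly-dT primer with a Quick Amp kit. Priming at the poly-A tail means that probes far from a transcript's 3' end read it less well. The scanner files showed 1 slide and 1 scan for all 3 arrays, so neither divides the times and no batch could be tested. Batches of culture, RNA extraction or labelling were not examined.

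Per the file headers, the deposited intensity values were produced by Agilent Feature Extraction 9.5.3.1: spatial and multiplicative detrending were switched on within each array, and spots near background received a small positive surrogate value. No scaling between arrays is recorded in the headers. Surrogates filled 16.3% of the non-control spots at 0 h, 15.8% at 2 h and 23.0% at 6 h. The deposited series value table, also intensity on a linear scale, listed 24753 of the 34127 non-control probes, and its values equalled the scanner signal averaged over a probe's spots, within 0.001 on the log2 scale, for 98.6% of them at 0 h, 98.7% at 2 h and 98.5% at 6 h. It is therefore not centred, its scale is that of the scanner signal, and a direction does not apply to single-channel values. Its column medians were 506.1 at 0 h, 521.8 at 2 h and 468.6 at 6 h. All 24657 probes well above background on at least 1 array were in it, and the rule that chose the listed probes is not given in the sources used here.

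Each array held 43118 non-control spots. Spots with the software's outlier flags were left out (257 at 0 h, 308 at 2 h and 468 at 6 h), the log2 processed signals of a probe's spots were averaged, and the array's 75th percentile over all non-control probes was subtracted. Before subtraction that percentile lay at a signal of 1348 at 0 h, 1430 at 2 h and 1275 at 6 h. This scaling assumes that the bulk of transcripts stayed level per unit of RNA, so a change shared by most transcripts would not be seen. The number of saturated probes was 0 on each array. Probes were named through the unversioned transcript accession in a RefSeq gene table (24827 probes), a current symbol (1276) or a unique synonym (500). The file's own name was kept for 5762 probes, and 1762 had no gene name. For genes with several probes (5593 genes), the probe with the highest mean signal over the 3 arrays was used. Probe positions are those in the files, on the human build hg18, and no annotation of that build was used here to place them in exons or untranslated regions.

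A log2 ratio was the difference of 2 scaled arrays. A probe well above background on only 1 of the 2 arrays gave a bound: the brighter array over the higher of the dim probe's own signal and the lowest signal well above background on the dim array, with 0 where that fell under 1-fold. A gene with no array of the pair well above background was not measured. With 1 array per group there is no estimate of the spread between cultures, so no test was run, and genes were counted by size alone at 2-fold. In the text "rose" and "fell" refer to genes at or past 2-fold between 2 arrays, or to lists that stood apart. Technical error was taken from repeated spots of one probe and from different probes of one gene.

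Before the data were examined, 36 gene lists were fixed. They covered stress responses (the PERK branch and integrated stress response, endoplasmic reticulum chaperones and ERAD, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, cytosolic heat shock proteins, NRF2 and oxidative stress, metallothioneins and zinc transport, p53 targets, apoptosis regulators, hypoxia), signalling (immediate early genes, cyclic AMP and CREB targets, NF-kappaB targets, interferon-stimulated genes, circadian clock, Notch, WNT and TGF-beta feedback targets, short-lived transcripts, retinoic acid response), metabolism (cholesterol, fatty acids, lysosome and autophagy, oxidative phosphorylation, glycolysis), growth (DNA replication, mitosis, histones, ribosomal proteins, ribosome biogenesis, proteasome) and cell identity (catecholamine handling, adrenergic and dopamine receptors, neuronal genes, noradrenergic regulators, mesenchymal and glial markers, immune and endothelial markers, housekeeping controls). A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was described as standing apart below percentile 2.5 or above 97.5. Such a percentile describes these arrays and is not a test of the exposure. Percentiles printed as 0 or 100 are rounded.

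The genes named were also fixed by rule beforehand. For each comparison with 0 h these were the 8 largest rises and 8 largest falls among genes with an official-type symbol and a probe well above background on both arrays and at or above the median of such probes, for 6 h vs 2 h the 5 largest of each, up to 4 members per list with the largest change at either time, and the 3 largest bounds per direction. Some genes that met the rule are not reported here. Other genes named are said to have been chosen after their values were seen.

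On simulated arrays with known changes, modelled on 6 h vs 0 h over 25498 genes, 50 of 50 genes raised 3-fold and 46 of 50 lowered 3-fold were counted, as were 50 of 50 raised 8-fold and 44 of 50 lowered 8-fold. Of the unchanged genes, 0 of 18244 were counted at 6 h vs 0 h and 0 of 18919 at 2 h vs 0 h. Of 100 random lists, 5 fell outside the limits for standing apart. For the overlap of the comparisons that share the 0 h array, 100 draws of unchanged arrays were simulated from the technical errors. They gave an overlap of 0 but, as with the unchanged genes above, technical error alone does not reach 2-fold, so they cannot show what the shared array adds.

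The alternatives tried were another scale (the median of probes above background on all arrays), quantile normalization, limma's normexp background correction with an offset of 50 followed by quantile normalization, the deposited value table, the median over a gene's probes, only brighter probes, no filter on dim probes, saturated probes kept, and random lists not matched on expression. A further one, dim probes at their measured value in place of the bound, was chosen after seeing the data. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with limma 3.58.1.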

Results

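The series followed gene expression in retinoic acid-differentiated SH-SY5Y neuroblastoma cells over 6 h of exposure to 3 mM norephedrine, a sympathomimetic amine also known as phenylpropanolamine. One-colour arrays were read at 0, 2 and 6 h, 1 array per time, so no difference has a replicate check. The 0 h array was the only unexposed sample, and no vehicle-treated culture of matched time was analysed here, so exposure and elapsed time changed together. Probes well above background numbered 23913 of 34127 at 0 h (70.1%), 24040 at 2 h (70.4%) and 21272 at 6 h (62.4%). The lowest signal called well above background was 16.2 at 0 h, 15.8 at 2 h and 32.0 at 6 h, so the 6 h array measured fewer dim transcripts. Repeated spots of one probe had a median SD of 0.045 (0 h), 0.041 (2 h) and 0.043 (6 h) on the log2 scale. Log2 ratios from different probes of one gene differed with a robust SD of 0.15 (2 h vs 0 h), 0.14 (6 h vs 0 h) and 0.13 (6 h vs 2 h). The spike-in controls had a fitted slope of 0.769 at 0 h, 0.987 at 2 h and 1.01 at 6 h, and no correction was made for it. These SDs are technical errors, and the spread between cultures is unknown.

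At 2 h the cells carried a large pulse of immediate early transcripts, the genes that growth factor and depolarising signals switch on without new protein synthesis. Of 31 measured members of that list, 17 rose and 1 fell, and the median log2 ratio was 1.15 (percentile 100 of matched random lists). The zinc finger factor EGR2 rose 17.3-fold, the synaptic gene ARC 11.6-fold and the AP-1 subunit FOS 11.3-fold. EGR3 and EGR4 were not well above background at 0 h and were at least 27.2-fold and 14.5-fold higher at 2 h. The member that fell was MYC, named after its values were seen, with a log2 ratio of -1.14. On the 6 h array the same list had a median of 0.00 (percentile 69.4), with 0 of 27 measured members past 2-fold in either direction. The EGR2 signal ran from 58.4 at 0 h to 1070 at 2 h and 62.4 at 6 h, and that of FOS from 223 to 2661 and 187. The EGR2 probe lies on chromosome 10 from 64241856 to 64241915 and the FOS probe on chromosome 14 from 74817967 to 74818026 (hg18).

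Some retinoic acid-responsive genes were also higher at 2 h. CYP26A1 and CYP26B1, the hydroxylases that clear retinoic acid and are direct targets of its receptors, rose 7.15-fold and 7.83-fold, and the retinaldehyde reductase DHRS3 rose 2.70-fold. The CYP26A1 probe (chromosome 10, 94827003 to 94827062, hg18) read 7051 at 0 h, 53450 at 2 h and 9660 at 6 h. TGM2, the tissue transglutaminase, rose 2.95-fold by its brighter probe, while its other probe gave log2 ratios of 0.30 at 2 h and -1.13 at 6 h. These were the 4 risers among 15 measured members, 0 fell, and 5 had ratios below 0. The list median was 0.32 at 2 h (percentile 100) and 0.18 at 6 h (percentile 99.7), where no member was past 2-fold. With no filter on dim probes the 2 h median was 0.15. Further retinoic acid targets, held out of that list, did not stand apart at 2 h (8 measured, median 0.05, percentile 74.4). By 6 h the log2 ratios to 0 h were 0.53 for CYP26A1, 0.25 for CYP26B1 and 0.63 for DHRS3.

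Several other signal-responsive lists stood apart at 2 h. Circadian clock genes had a median of 0.59 (percentile 100), with 2 of 15 members past 2-fold: the period gene PER1 rose 2.98-fold, and the repressor BHLHE40 was at least 2.25-fold higher. Notch, WNT and TGF-beta feedback targets had a median of 0.46 (percentile 100) with 3 of 20 members risen, namely the Notch target HES1 (3.40-fold) and the inhibitors of differentiation ID4 (2.18-fold) and ID1 (2.00-fold). Metallothioneins and zinc transporters had a median of 0.53 (percentile 100). The zinc exporter SLC30A1 rose 2.45-fold and the metallothionein MT1E 2.29-fold, and MT1M was at least 4.39-fold higher. Metallothionein transcripts are similar in sequence, so their probes are not fully separate readings. Cyclic AMP and CREB targets had a median of 0.37 (percentile 100), with NR4A1 (3.24-fold) and PER1 risen among 18 members, genes shared with the immediate early and clock lists. With no filter on dim probes that median turned to -0.036. Short-lived transcripts, which drop when transcription is blocked and overlap the immediate early list, had a median of 0.54 (percentile 100) with 7 of 22 members risen, among them JUNB (3.20-fold) and ZFP36 (2.55-fold), and 1 fallen. Over the alternatives that median ran from 0.34 to 0.76. Inflammatory and NF-kappaB targets had a median of 0.25 (percentile 99.6) with 0 of 13 members past 2-fold, and with no filter on dim probes that median was 0.084. On the 6 h array the medians of these lists were -0.04 (clock), -0.02 (Notch, WNT and TGF-beta), 0.02 (metallothioneins), 0.00 (cyclic AMP), 0.06 (short-lived) and 0.00 (NF-kappaB), and these 6 lists no longer stood apart. With measured values in place of bounds the 6 h medians were -0.08 (Notch, WNT and TGF-beta), 0.01 (cyclic AMP), 0.08 (short-lived) and 0.05 (NF-kappaB).

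Genes of DNA replication were lower at 2 h. Of 30 measured members 5 fell, 0 rose and 29 had ratios below 0, with a median of -0.81 (percentile 0). Among those that fell were 3 subunits of the replicative helicase, MCM6 (2.46-fold), MCM5 (2.34-fold) and MCM2 (2.14-fold), and UHRF1, a factor that keeps DNA methylation through replication (2.10-fold). A 2nd probe of MCM5 gave -1.24 and a 2nd probe of UHRF1 -1.14 on the log2 scale. At 6 h all 30 members were still below 0, with a median of -0.47 (percentile 0) and none past 2-fold; MCM6 stood at -0.58. The mitosis list had a median of -0.31 at 2 h (percentile 0) and -0.20 at 6 h (percentile 0), with 0 of 30 members past 2-fold at either time; the spindle checkpoint kinase BUB1B had log2 ratios of -0.80 and -0.48. Ribosome biogenesis genes had a median of -0.22 at 2 h (percentile 0.02) and -0.06 at 6 h (percentile 7.25), with UTP20, a small-subunit processing factor, at -0.81 at 2 h. Canonical histones had a median of 0.06 at 2 h (percentile 79.6) and -0.24 at 6 h (percentile 0.44), with H1-2, a linker histone, at -0.60 at 6 h. With only brighter probes the 6 h median was -0.11. Histone genes are near-identical copies, and the 2 probes of H2AC6 above background gave log2 ratios of 0.998 and 0.22 at 2 h. Copying from a poly-dT primer reads mainly transcripts with a poly-A tail, so these values may not stand for all histone transcripts.

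Over all genes, 276 were at least 2-fold higher and 359 at least 2-fold lower at 2 h than at 0 h, of 18602 measured. Bounds made up 60 of the higher and 68 of the lower genes. Beyond the lists, the largest rises among brighter probes included GDF10, a bone morphogenetic protein relative (13.6-fold), TNFRSF12A, the receptor of the cytokine TWEAK (signal 856 to 7270), and the transcriptional coregulator SERTAD1 (6.30-fold). HS3ST2, a heparan sulphate sulphotransferase, was at least 5.39-fold higher. The largest falls were CRTAC1, an extracellular matrix protein (7.35-fold), the polyadenylation factor subunit CSTF3 (4.11-fold, and a log2 ratio of -1.22 by its other probe), HPDL (3.59-fold), CPNE5 (3.28-fold), the semaphorin receptor PLXNA4 (3.26-fold), the endothelin receptor EDNRA (3.23-fold), RSPO4 (3.01-fold) and the centromere protein CENPK (2.89-fold). Bounds were at least 7.33-fold lower for HS6ST3, 6.77-fold for NECAB2 and 4.64-fold for BRDTP1. Where a 2-fold gene had another probe above background, all its probes had the same sign for 68 of 72 genes. With only brighter probes the counts were 116 higher and 89 lower, and after normexp and quantile normalization 107 and 81, which turned the share of higher genes from 43.5% to 56.9%.

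**Figure D1:**
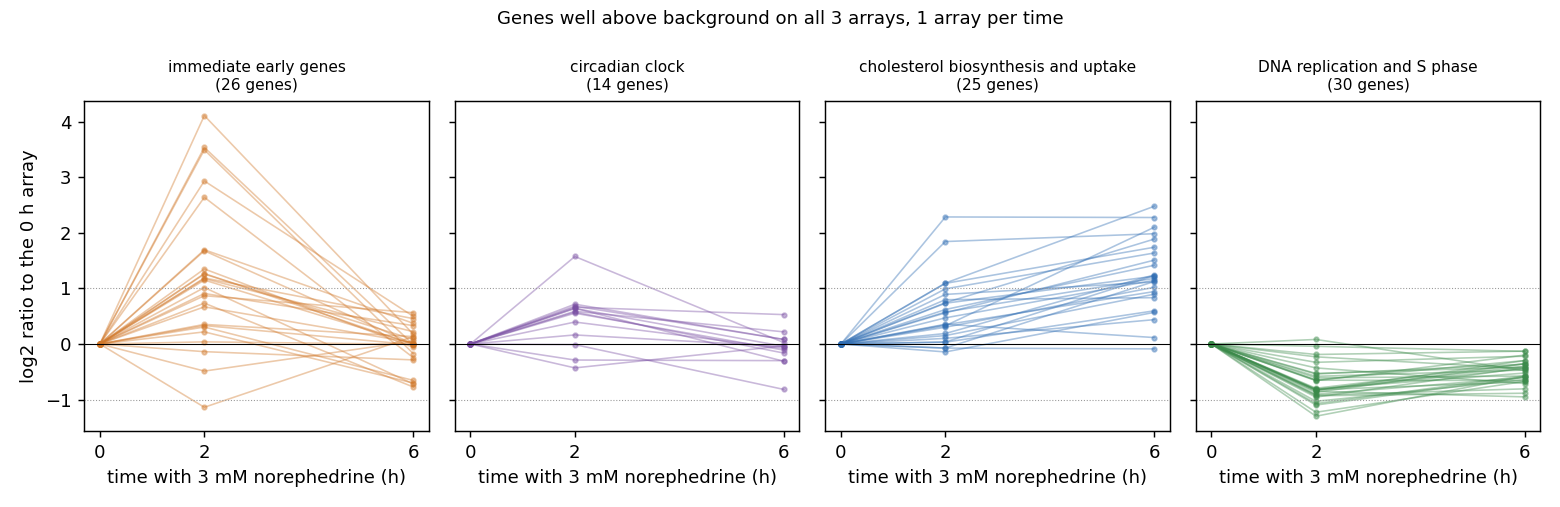
Each line is 1 gene, drawn as its log2 ratio to the 0 h array (vertical axis) against hours with 3 mM norephedrine (horizontal axis), for genes of 4 lists that were well above background on all 3 arrays. Each time is 1 array, so there are no error bars, and dotted lines mark 2-fold. Most immediate early genes (26 drawn) and clock genes (14) peak at 2 h, cholesterol genes (25) are higher at 6 h than at 2 h in 22 cases, and genes of DNA replication (30) lie below 0 at 6 h.

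At 6 h the genes of cholesterol synthesis and uptake were the main group that stood out. Of 25 measured members 17 rose, 0 fell and 24 had ratios above 0, with a median log2 ratio of 1.18 (percentile 100). The reductase DHCR7 rose 5.57-fold, the sterol sensor INSIG1 3.96-fold, the early enzyme HMGCS1 3.70-fold, the methyl sterol oxidase MSMO1 3.34-fold and the sterol carrier STARD4 3.11-fold. The DHCR7 signal ran from 3894 at 0 h to 8834 at 2 h and 20530 at 6 h (probe on chromosome 11, 70823162 to 70823221, hg18). At 2 h the list median was 0.47 (percentile 100), with 4 of 25 members risen, among them INSIG1 (3.59-fold), DHCR7 (2.14-fold) and MSMO1 (2.13-fold). Genes of fatty acid synthesis and oxidation had a median of 0.07 at 2 h (percentile 85.4) and 0.23 at 6 h (percentile 100). Of 20 members, 15 were above 0 at 6 h. The 5 below 0 included the oxidation genes CPT2, ACADM and CPT1A, named after their values were seen. At 6 h the desaturases FADS2 (2.15-fold) and SCD (2.11-fold) rose and the lipase inhibitor ANGPTL4 fell 2.18-fold, while the synthase FASN stood at 0.94 on the log2 scale.

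Lysosome and autophagy genes had a median of 0.14 at 2 h (percentile 99.2) and 0.27 at 6 h (percentile 100). FLCN, folliculin, which acts in nutrient sensing at the lysosome, rose 2.18-fold at 2 h and 2.35-fold at 6 h, and the sialidase NEU1 rose 2.01-fold at 6 h. Another FLCN probe gave log2 ratios of 0.89 and 0.87, under 2-fold at both times. The GTPase RRAGD had log2 ratios of 0.85 and 0.93. The other 32 members measured at 2 h and 31 at 6 h were within 2-fold.

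Genes of the PERK branch and integrated stress response had a median of 0.10 at 2 h (percentile 94.8) and 0.35 at 6 h (percentile 100). At 2 h GDF15, a stress-induced secreted factor, rose 3.31-fold, the phosphatase subunit PPP1R15A 2.21-fold and the transcription factor DDIT3 2.14-fold, and NUPR1 fell 2.45-fold, of 21 measured members. At 6 h GDF15 was 2.01-fold higher and the other 20 members were within 2-fold. Endoplasmic reticulum chaperones and ERAD genes did not stand apart at 2 h (median -0.03, percentile 22.9) or 6 h (median 0.01, percentile 49.3), and 0 of 29 members were past 2-fold. The chaperone HSPA5 had log2 ratios of -0.41 and -0.55 and its cofactor SDF2L1 -0.69 and -0.59. Amino acid synthesis and transport genes had a median of -0.35 at 2 h (percentile 0) and 0.27 at 6 h (percentile 100). At 2 h the cystine transporter SLC7A11 fell 2.75-fold and the glycine transporter SLC6A9 2.51-fold, and the other 19 members were within 2-fold. At 6 h SLC7A11 was at 0.99. Cytosolic aminoacyl-tRNA synthetases had a median of -0.26 at 2 h (percentile 0) and 0.14 at 6 h (percentile 98.9), with 0 of 20 members past 2-fold; YARS1 had log2 ratios of -0.49 and 0.48.

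The p53 target list had a median of 0.26 at 2 h (percentile 100) and 0.17 at 6 h (percentile 99.9). It shares GDF15, BBC3, SESN2, PMAIP1 and TNFRSF10B with the integrated stress list, so these lists are not separate readings. GDF15 and the growth arrest gene GADD45A (2.19-fold) rose at 2 h, and GDF15 alone at 6 h. The hypoxia list had a median of 0.22 at 2 h (percentile 99.9) and 0.23 at 6 h (percentile 100). The lysyl hydroxylase JMJD6 rose 2.74-fold and the oxygen sensor EGLN3 fell 3.20-fold at 2 h, and 0 of 20 members were past 2-fold at 6 h. Ribosomal protein genes had a median of 0.15 at 2 h (percentile 99.98) and 0.12 at 6 h (percentile 97.8), with 31 of 32 members above 0 at each time and none past 2-fold. At 6 h the median dropped to 0.033 with quantile normalization.

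Lists tied to the cells' identity and to the drug's usual targets did not stand apart at either time. Catecholamine synthesis and transport had medians of -0.01 at 2 h (percentile 39.5) and -0.08 at 6 h (percentile 5.04), with 0 of 17 members past 2-fold. In it DDC, the decarboxylase that forms dopamine, had log2 ratios of -0.93 and -0.43, and PNMT, which forms adrenaline, -0.50 and -0.89. Of 15 adrenergic, dopamine and trace amine receptors 8 were measured, with medians of 0.01 (percentile 63.5) and 0.00 (percentile 47.7). Neuronal genes had medians of -0.01 (percentile 28.9) and 0.04 (percentile 60.8), and noradrenergic regulators 0.01 (percentile 44.6) and 0.11 (percentile 95.4). Mesenchymal and glial markers had medians of 0.00 at both times (percentiles 64.7 and 58.8), where bounds under 1-fold count as 0. With measured values in place of bounds these medians were 0.15 and 0.05. The filament gene VIM fell 2.43-fold and the transcription factor SNAI2 rose 2.27-fold at 2 h. Immune and endothelial markers had medians of -0.18 (percentile 23.9) and 0.00 (percentile 69.7).

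Of the remaining stress and metabolic lists, heat shock proteins had medians of 0.11 (percentile 97.1) and 0.09 (percentile 95.1), with DNAJB1, a co-chaperone, at 0.76 at 2 h. NRF2 targets had medians of 0.00 at 2 h (percentile 57.5) and 0.00 at 6 h (percentile 51.9). Of that list the quinone reductase NQO1 fell 2.05-fold at 6 h, and NFE2L2, which encodes NRF2 itself, rose 2.68-fold at 2 h from a dim signal. Apoptosis regulators had medians of 0.08 at both times (percentiles 93.7 and 94.3). The BCL2 family member BIK was at least 2.61-fold higher at 2 h. Oxidative phosphorylation had medians of -0.01 (percentile 29.8) and -0.03 (percentile 6.08). Glycolysis had 0.03 (percentile 63.9) and 0.06 (percentile 70.9), interferon-stimulated genes 0.01 (percentile 68.8) and -0.08 (percentile 32.4), and proteasome subunits 0.06 at both times (percentiles 76.6 and 64.8). Housekeeping controls had medians of 0.01 (percentile 41.0) and 0.06 (percentile 68.7). Of the 36 lists, 13 stood apart as higher and 5 as lower at 2 h, and 10 as higher and 3 as lower at 6 h.

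**Figure D2:**
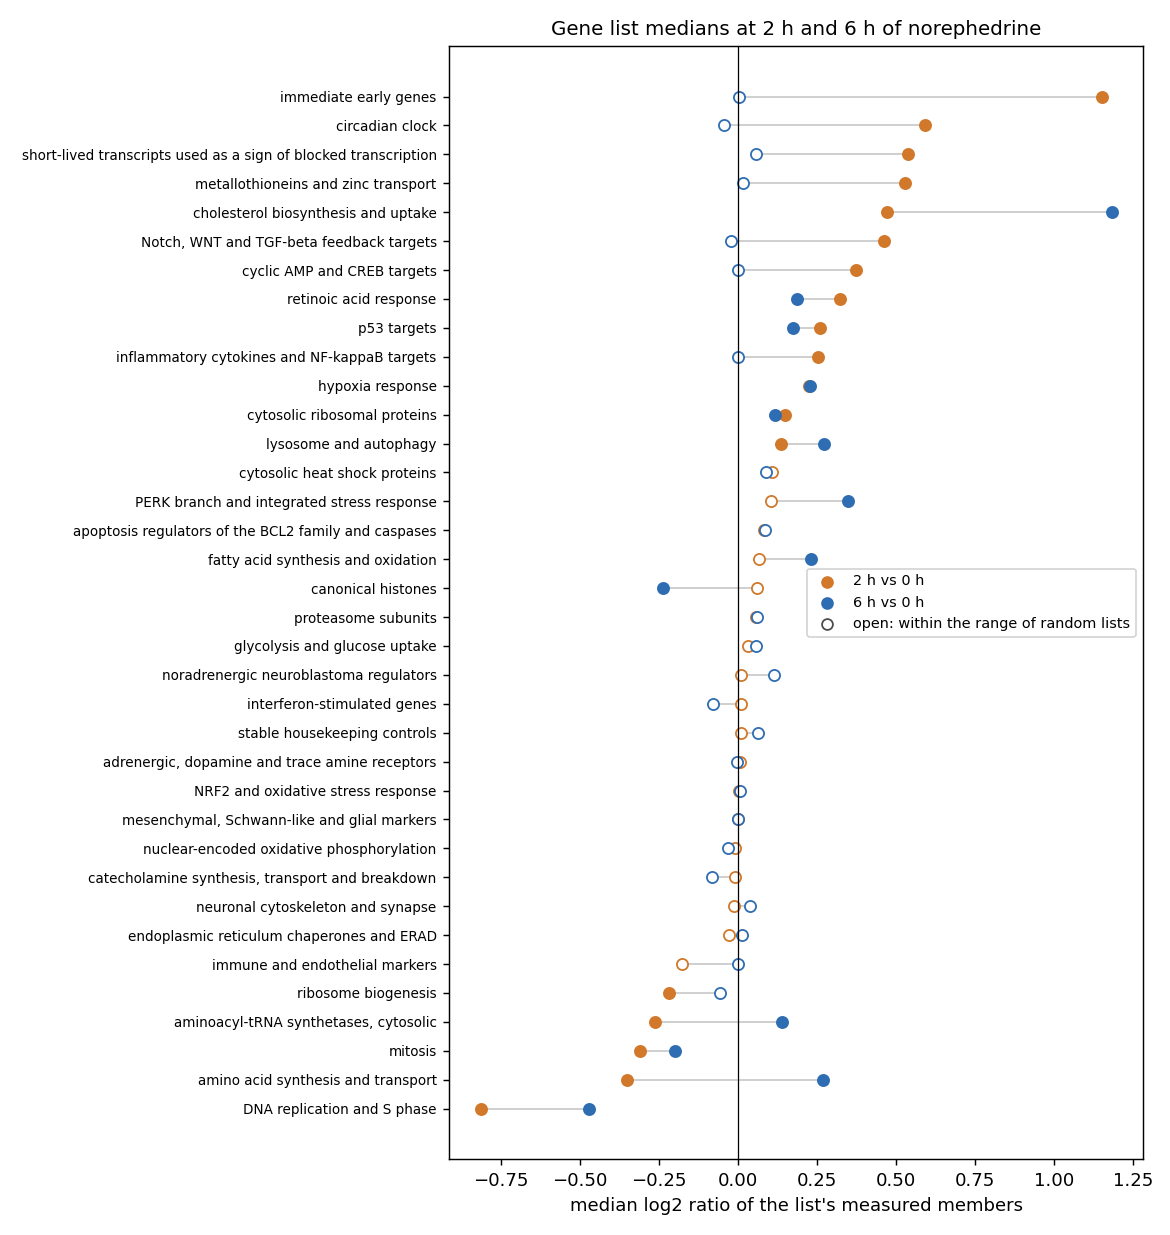
Median log2 ratio to the 0 h array (horizontal axis) of the measured members of each of 36 gene lists, at 2 h (orange) and 6 h (blue), 1 array per time. Filled points stood apart from matched random lists and open points did not. Immediate early genes lead at 2 h (1.15) and return to 0.00 at 6 h, while cholesterol genes go from 0.47 to 1.18.

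Over all genes, 210 were at least 2-fold higher and 152 at least 2-fold lower at 6 h than at 0 h, of 18263 measured. Outside the lists, the flavin monooxygenase pseudogene FMO6P was 3.12-fold higher. The largest falls among brighter probes were the T-box factor TBX1 (4.80-fold), the gluconate kinase IDNK (2.75-fold), CSTF3 (2.39-fold, and -0.96 on the log2 scale by its other probe), the complement component C5 (2.36-fold), FGFBP3 (2.31-fold), ANGPTL4, CPNE5 (2.17-fold) and the ribokinase RBKS (2.12-fold). Bounds were at least 5.09-fold higher for ADGRF1, 5.07-fold for OR2B6 and 4.97-fold for KDM5A, and at least 3.84-fold lower for MDH1B, 3.05-fold for CRYGA and 2.96-fold for ABCC3. Bounds made up 106 of the 210 higher genes, and all 106 genes above background at 6 h alone passed 2-fold, against 60 of 445 such genes at 2 h. The lowest signal well above background was 32.0 at 6 h and 16.2 at 0 h. A gene above background at 6 h alone therefore passes 2-fold almost by construction. That all 106 passed follows from these limits and does not show larger changes than at 2 h. A bound never exceeds the measured ratio, so the signals of these genes did differ by at least 2-fold. How far noise in dim signals adds to such calls was not tested. Another 62 higher genes were in the dimmest of 5 brightness groups, so 80.0% of the higher genes were dim or bounds, against 43.1% at 2 h. Of the 152 lower genes at 6 h, 36 were bounds and 57 were in the dimmest group. Of the 359 lower genes at 2 h these were 68 and 119. With only brighter probes the counts were 36 higher and 14 lower. After normexp and quantile normalization they were 32 and 16, and quantile normalization alone moved the share of higher genes from 58.0% to 69.1%. With dim probes at their measured value, 210 were higher and 547 lower, which turned that share to 27.7%.

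Between 2 h and 6 h the immediate early genes fell back and the sterol and amino acid genes went up. EGR2 had a log2 ratio of -3.93 at 6 h vs 2 h, FOS -3.66, ARC -3.55, GDF10 -3.46 and TNFRSF12A -3.33. The list medians were -1.14 for immediate early genes (16 of 31 members fallen, 1 risen, percentile 0), -0.60 for the clock, -0.52 for metallothioneins and -0.51 for Notch, WNT and TGF-beta targets (percentile 0 for each). With only brighter probes the metallothionein median was -0.09, and after normexp and quantile normalization the medians were -0.70 for immediate early genes and -0.36 for the clock. The largest rises among brighter probes included CRTAC1 (2.10), FMO6P (1.73), PLXNA4 (1.71) and EDNRA (1.71). CRTAC1, PLXNA4 and EDNRA had fallen at 2 h, and EDNRA stood at 0.01 against 0 h by 6 h. PLXNA4 also stood at 0.01 by its brightest probe, but some of its other probes stayed below 0. Amino acid genes had a median of 0.61 (19 of 20 above 0, percentile 100), cholesterol genes 0.65 (6 of 25 risen, percentile 100), aminoacyl-tRNA synthetases 0.37 (percentile 100) and DNA replication 0.23 (percentile 100). Over all genes 286 were higher and 248 lower at 6 h than at 2 h, of 18357 measured. Bounds made up 105 of the higher genes. With lowest signals well above background of 32.0 at 6 h and 15.8 at 2 h, such bounds pass 2-fold almost by construction. With only brighter probes 43 were higher and 92 lower, and normexp with quantile normalization turned the share of higher genes from 53.6% to 33.8%.

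The changes at 2 h and 6 h overlapped. Of 18169 genes measured in both comparisons with 0 h, 14 were higher at both times and 49 lower at both, against 1.39 and 3.00 for independent lists. Lists that share the 0 h array are not independent, and how much of the overlap comes from that array was not tested. None went in opposite directions past 2-fold. The numbers higher and lower at both times were 5 and 3 after normexp and quantile normalization, 7 and 4 with only brighter probes, and 241 and 211 with no filter on dim probes. The genes higher at both times included INSIG1, DHCR7, MSMO1, GDF15 and FLCN, and those lower at both included TBX1, CSTF3, CPNE5, RSPO4 and FGFBP3, with MDH1B, CRYGA, ABCC3 and BRDTP1 as bounds at 1 or both times. For FLCN at both times and CSTF3 at 6 h the other probe was under 2-fold. Across 16212 genes, which are not independent replicates, the 2 sets of log2 ratios had a Pearson r of 0.475 and a Spearman rho of 0.496. Their covariance was 0.058, against 0.011 from the technical error of the shared 0 h array estimated between probes and 0.0021 estimated between spots. With 1 array at 0 h the part due to that culture could not be separated.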

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

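The medians of 2 gene lists stood apart from matched random lists in opposite directions at the 2 times, and the difference between the times was not tested, since each time is 1 array. Amino acid synthesis and transport genes had a median log2 ratio to 0 h of -0.35 at 2 h and 0.27 at 6 h, and 18 of 21 members were below 0 at 2 h against 17 of 21 above 0 at 6 h. Members chosen after their values were seen included the asparagine synthetase ASNS (-0.48 and 0.27), the mitochondrial folate enzyme MTHFD2 (-0.49 and 0.42) and the leucine transporter SLC7A5 (-0.49 and 0.46). SLC38A2 (0.58 and 0.66) and SLC3A2 (0.55 and 0.60) were above 0 at both times. Cytosolic aminoacyl-tRNA synthetases had a median of -0.26 at 2 h and 0.14 at 6 h, with 18 of 20 members below 0 at 2 h and 16 of 20 above 0 at 6 h. Over the alternatives the amino acid median ran from -0.37 to -0.33 at 2 h and from 0.25 to 0.30 at 6 h, and the synthetase median from -0.28 to -0.24 and from 0.12 to 0.17. None of the alternatives scaled the arrays on the spike-ins. On the brighter spike-ins both 6 h medians would turn negative, so their sign depends on the scale. No explanation was tested for these lists.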

How the results depend on the processing

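Counts of 2-fold genes moved with the treatment of dim probes and with normexp and quantile normalization together, while most list medians moved little. After normexp and quantile normalization 107 genes were higher and 81 lower at 2 h vs 0 h, 32 and 16 at 6 h vs 0 h, and 48 and 94 at 6 h vs 2 h, with 5 higher and 3 lower at both times. All 107, 32 and 48 higher genes were also counted in the main setting. With only brighter probes the counts were 116 and 89, 36 and 14, and 43 and 92, with 7 and 4 shared. Fewer genes can be counted under both by construction. With no filter on dim probes they were 589 and 934, 4501 and 667, and 4759 and 632, with 241 and 211 shared; surrogate values differ between arrays and enter there. Quantile normalization left 31 genes lower at both times. With dim probes at their measured value, chosen after seeing the data, 547 were lower at 6 h vs 0 h, 604 at 6 h vs 2 h and 176 at both times. The cyclic AMP and CREB median at 2 h turned to -0.036 with no filter, where the NF-kappaB median was 0.084. The ribosomal protein median was 0.0997 at 2 h with quantile normalization and 0.091 with normexp, and at 6 h 0.15 with the median as scale, 0.033 with quantile normalization and 0.045 with normexp. The cause of these shifts was not tested. Keeping saturated probes changed nothing, since there were 0. The deposited value table moved none of the 8 counts or 108 list medians past the limits set. Random lists not matched on expression changed the side of 5 of 108 percentiles. No setting moved the median of all genes by 0.1 or more on the log2 scale, and no setting scaled the arrays on the spike-ins. Leaving out an array was not possible with 1 per time, and no paired analysis was possible because each group holds 1 array.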

Other observations

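The tests of held-out gene lists below were fixed before their values were seen, and those on scaling and on the spread of signals were chosen after the result was seen. Genes named from these lists were chosen after their values were seen.

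Targets of ERK signalling and the serum response factor that were in none of the fixed lists also peaked at 2 h. Their median log2 ratio to 0 h was 0.43 at 2 h, with 13 of 17 members above 0, and 0.03 at 6 h (percentile 80.4). The immediate early factor CSRNP1 (2.84) and the ERK feedback inhibitor SPRY4 (1.29, and 0.39 by its other probe) rose at 2 h, the inhibitor SPRY2 stood at 0.80 and the focal adhesion gene VCL at 0.65, and the urokinase receptor PLAUR fell (-1.07). ETV4 (-0.01) and ETV5 (0.02) stayed level at 2 h, and RHOB (-0.33) and EDN1 (-0.16) were below 0. Of the targets of the liver X receptor, a sensor of oxidised sterols, the cholesterol exporters ABCG1 (2.83-fold) and ABCA1 (2.21-fold) rose at 2 h and stood at 0.11 and 0.17 at 6 h. As a list the 7 measured targets did not stand apart at 2 h (median 0.14, percentile 89.1), and 2 of them were below 0.

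The immediate early pulse at 2 h kept a median log2 ratio of at least 0.89 under every alternative, so it did not depend on these processing choices. All alternatives reprocess the same arrays and left the median of all genes nearly unchanged. They could hardly have removed a shift of that size, and a fault of the 2 h array stays untested. A hypothesis is growth factor-type signalling through ERK and the serum response factor, and the held-out targets of that path lay at percentile 100 of matched random lists. The held-out targets are of the same kind as the immediate early list, and CSRNP1 among them is itself an immediate early factor. A high percentile was therefore likely once that list had risen. It does not separate the ERK path from other signals that switch on such genes. Renewed medium with fresh retinoic acid may have added to the pattern, given CYP26A1, CYP26B1 and DHRS3. Held-out retinoic acid targets lay at percentile 74.4, with only 8 of 13 measured, which leaves this open. Without a vehicle-treated array at 2 h, handling of the cells and norephedrine cannot be told apart as the trigger.

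The higher cholesterol genes at 6 h kept a median of at least 1.15 under every alternative, so they did not depend on these processing choices. As for the 2 h pulse, the alternatives could hardly have removed a shift of that size, and a fault of the 6 h array stays untested. A hypothesis is activation of SREBP2, the transcription factor that responds to low sterol in the endoplasmic reticulum: held-out SREBP2 targets lay at percentile 100, with a median of 0.68 and 12 of 12 members above 0, among them MMAB (1.39) and the lysosomal cholesterol carrier NPC2 (0.81). The mixed list of fatty acid synthesis and oxidation also stood apart as higher at 6 h (median 0.23). The held-out SREBP2 targets therefore do not single out SREBP2 from related factors. If the liver X receptor had sensed low sterol, its targets should have been lower, but they lay at percentile 89.3 with a median of 0.11 and 6 of 7 members above 0. As a set these targets did not fall, but whether the receptor was active enough at 0 h to allow a fall was not tested. Whether SREBP2 itself acted stays open. It also stays open whether sterol was low in 1 compartment of the cell or SREBP2 was activated in another way. Any effect of culture time without drug stays open too.

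The spike-in control RNAs did not behave alike on the 3 arrays. Per the scanner software's own fit, their slope was 0.769 at 0 h, 0.987 at 2 h and 1.01 at 6 h. The dim spike-in that read 15.3 at 2 h and 11.4 at 6 h read 127 at 0 h, while the brightest read 85550 at 0 h against 109800 and 106000. Spike-ins ranked 6 to 10 from the dimmest had unscaled log2 ratios to 0 h of 0.35 to 0.40 at 2 h and 0.25 to 0.36 at 6 h. The 75th percentile used for scaling stood at 10.40 (0 h), 10.48 (2 h) and 10.32 (6 h) on the log2 scale. A scale set on these 5 brighter spike-ins would lower the log2 ratios to 0 h at both times. Small positive medians at 6 h, such as 0.27 for amino acid genes and 0.14 for aminoacyl-tRNA synthetases, would then turn negative. The dimmer spike-ins read lower at 2 h and 6 h than at 0 h, no spike-in scale was run, and which scale is right is not known. A compressed scale of the 0 h array for all probes would narrow the spread of its gene signals too, yet over 21114 probes above background on all arrays the SD of log2 signal at 0 h was 0.983 times that at 2 h. What set the spike-ins apart was not tested, and no biological explanation was tested either.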
